A study of Caenorhabditis elegans with 5 samples.

How the data were processed

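Whole synchronized adult worms of the strain N2 were sampled under 5 conditions, and total RNA was sequenced from libraries made by a standard Illumina HiSeq2000 protocol, per the labels. Worms had been kept for 3 weeks on the respective food before synchronized larvae were moved to 15 plates per condition, and 5 plates were combined into each biological sample, per the labels. The labels state 3 biological replicates per condition, and the series' design text says mostly 3. The aligner, the quantifier, the genome build and the annotation are not given in the sources used here, so no coordinates are printed.

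Values per condition are the authors' mean FPKM per gene, per the file headers. Each of the 4 comparison tables holds the same means, the ratio of the means and its log2 value, which the authors deposited, and a probability score per gene from a tool the file headers do not name. The comparison tables also list a gene length in bases, per the file headers, which need not be whole and is used here as given. The log2 ratio in the authors' tables equalled the log2 quotient of their means, within a small rounding tolerance, in 100% of genes. The probability score runs from 0 to 1 and is not a p-value. In the deposited table of 10 µM over HT115_2 it has no missing score, a median of 0.293 and a highest value of 0.994, while the other 3 tables have 5689 to 6076 missing scores and reach 1, so the scales differ. A probability threshold of 0.8 was applied to the authors' deposited tables, and 0.8 was chosen after their values had been seen.

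All deposited means in HT115_1 were multiples of 0.01 divided by 2, and in the other 4 conditions of 0.01 divided by 3, which are the steps of averages over 2 and 3 replicates. The comparison tables enter a replicate at 0 as 0.01, which gives the number of replicates at 0 for each gene. With that rule their means equalled the condition means, within a small rounding tolerance, in 100% of genes. The exception was the table of the 2 doses, where 96.8% of values at 0.1 µM and 55.8% at 10 µM were equal. The largest difference there was 4.29%, and the condition means were used throughout. The fragments per library were estimated from genes with a single replicate above 0, from the step in FPKM times length. The estimates were 11300000 in HT115_1, 11200000 in OP50, 11100000 in HT115_2, 11100000 at 0.1 µM and 11200000 at 10 µM. They are approximate, since 61.8% to 72.8% of the values used lay within 0.15 of a whole number of fragments. Values spread evenly would give 30%, but the step was fitted to these same values, which raises the share, so the 2 are not directly comparable.

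The planned count and linear-model tests could not be used because the values are means per condition, and the rule fixed for that case was applied. Log2 ratios were taken of FPKM with a pseudocount of 0.5, for genes of at least 1 FPKM in either condition, and genes were counted at 2-fold. The diet pair and the cadmium set list different genes and were processed separately, so ratios between HT115_1 and the cadmium set cross sets. Of 19366 gene identifiers, 97.7% received a symbol from a reference table of gene names. Symbols that belong to more than 1 identifier with different values are given with the identifier, and 80 genes share all their values with another gene. Every column of means was assigned to a condition.

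The 33 gene lists covered metal and stress responses, detoxification, lipid and propionate metabolism, defence, cuticle, germ line, tissue markers and housekeeping. These lists were fixed before the data were examined. The processing alternatives were fixed then too, except those stated below to have been chosen after seeing the data. The threshold on the authors' probability was likewise chosen later. Of the lists, 2 of organelle and structural RNA had no member in the files, and 31 were compared. The percentile of a list's median was taken among 10000 random lists matched in 20 bins of mean expression. Chance places about 5% of lists beyond the outer 2.5% limits on either side if genes vary independently, which members of a list need not do. Between the HT115 conditions, the same food in separate sets, 16 of the 31 lists lay beyond these limits. The numbers were 14 for HT115_1 over OP50, 18 for 0.1 µM over HT115_2, 12 for 10 µM over HT115_2 and 17 for 10 over 0.1 µM. The named genes were, per comparison, the 10 highest and 10 lowest log2 ratios among symbols of the letters-and-number kind with at least 10 FPKM in the higher condition. To these were added every detected member of the metal response, propionate shunt and vitellogenin lists, and the 2 highest and 2 lowest members of every other list with at least 5 FPKM. Members of long lists may be left out. For a list whose direction depends on scaling, the median relative to all genes is given.

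Alternatives were pseudocounts of 0.1 and 1, no filter or 5 FPKM, 1.5- and 4-fold, rescaling by the median ratio or by a trimmed mean (trims of 30% and 5%), and the authors' probability. Length centring, which subtracts a running median of the log2 ratio over gene length drawn through 30 bins, HT115_1 as the control of the cadmium doses, and HT115_2 in place of HT115_1 against OP50 were chosen after seeing the data. A list median was taken as moved when it differed by at least 0.3, also chosen at that stage, and a correlation when it left the 95% bootstrap interval over genes. The scripts were tested on simulated data. For 0.1 µM over HT115_2, with 12784 simulated genes, 79.0% of 100 genes changed 2.5-fold and 99.0% of 100 changed 4-fold were counted, against 0.016% of unchanged genes. The simulated noise was a fixed setting, not taken from these data, so the percentages check the scripts only. They do not give the share of unchanged genes counted in the deposited means. Between the HT115 conditions, the same food, 286 of 13119 genes were 2-fold higher and 1482 lower. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.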

Results

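Gene expression was measured by RNA sequencing in whole, synchronized adult Caenorhabditis elegans of the wild-type strain N2 under 5 conditions. Worms ate Escherichia coli, either OP50, the usual laboratory food, or HT115, the strain that carries double-stranded RNA constructs in feeding RNA interference. A first HT115 condition, HT115_1, was set against OP50. A second HT115 condition, HT115_2, was the control for HT115 with cadmium chloride at 0.1 µM and at 10 µM. The labels state 3 biological samples per condition, each pooled from 5 plates. The decimals of the deposited means are those of an average over 3 libraries in 4 of the conditions and over 2 libraries in HT115_1. Mean FPKM values, fragment counts normalised to gene length and library size, were listed for 19028 genes in the diet pair and 18895 genes in the cadmium set. Between 11301 genes in OP50 and 12826 in HT115_2 had a mean of at least 1 FPKM. From the smallest steps of the values, each library held approximately 11100000 to 11300000 fragments.

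The values used were the authors' means, with no value per replicate. No test, error or p-value can be given, and whether a difference exceeds the spread between replicates cannot be assessed. Higher and lower below describe these means. Ratios are on the log2(FPKM + 0.5) scale, which understates differences of weakly expressed genes, and a gene was counted at 2-fold or more. The median log2 ratio of a gene list is given relative to the median of all genes compared, with its percentile among 10000 random lists of matched expression. A percentile is a description of these libraries.

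HT115_1 against OP50 asks how the bacterial food affects the transcriptome of unexposed adults. Of 12280 genes compared, 495 were at least 2-fold higher in HT115_1 and 77 were lower. Genes of sperm were higher as a group in HT115_1, and genes of the cuticle collagens were lower as a group. Among the named genes with the largest differences were the C-type lectin gene clec-197 (WBGene00008202), 11.6-fold higher in HT115_1 at 13 against 0.670 FPKM, and pud-1.2 (WBGene00021236), 6.29-fold lower at 22.7 against 145 FPKM. Several of these differences do not hold for HT115_2, the same food in the other set. That comparison needs a gene listed in both sets with at least 1 FPKM in HT115_2 or OP50, which 399 of the 495 higher genes met. Of these 399, 294 were also 2-fold higher in HT115_2 than in OP50. Higher genes under 1 FPKM in both HT115_2 and OP50 were left out and not counted as failing to repeat. Of the 77 genes lower in HT115_1, 76 could be compared, of which 13 were also 2-fold lower in HT115_2 and 40 had the opposite sign. The median of all genes was 0.52 in HT115_2 over OP50, with 2648 genes 2-fold higher and 193 lower. That shift favours agreement among the higher genes and disagreement among the lower ones, and both ratios share OP50. Of the 2 examples, clec-197 stood at 2.62 FPKM and pud-1.2 at 295 FPKM in HT115_2.

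The 60 sperm genes, mostly major sperm proteins and genes required in spermatogenesis, had a median 0.55 above that of all genes (percentile 100). Of these, 9 were 2-fold higher in HT115_1 and 0 were lower. In HT115_2 against OP50, their median was -0.38 relative to all genes, with 8 of 59 higher and 1 lower, and their median level was 13.3 FPKM in both. An example is ssq-3, at 5.02 against 2.00 FPKM. The sperm gene with the largest ratio, ssp-9 (WBGene00006038), was listed at 0 in OP50 and rested on 1 of the 2 HT115_1 libraries, with a mean of 37.9 FPKM. Heat shock genes had a median 0.22 above all genes (percentile 99.9), with 4 of 17 at least 2-fold higher, and 0.038 above all genes in HT115_2, with 4 of 16 higher and 1 lower. Among them was the small heat shock gene hsp-16.48, present as 2 identical copies whose reads cannot be separated, at 7.82 against 3.04 FPKM.

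Cuticle collagens, the structural proteins of the worm's surface, had a median of -0.38 relative to all genes (percentile 0). In HT115_1, 11 of the 122 were lower, among them dpy-4 at 7.35 against 18.5 FPKM and col-71 at 5.42 against 13.5 FPKM. Another 5 were higher, led by dpy-14 at 32.4 against 8.02 FPKM and col-74 at 11.8 against 3.60 FPKM. In HT115_2, 41 of 125 collagens were higher than in OP50 and 4 lower, but their median lay only 0.084 above that of all genes (0.52). There col-71 stood at 11.6, dpy-4 at 13.7 and col-74 at 1.47 FPKM. C-type lectins, many of which respond to microbes, were spread in both directions, with 20 of 99 higher and 4 lower in HT115_1. Besides clec-197, clec-219 stood at 7.77 against 0.470 FPKM, while clec-209, listed as 2 copies with the same values, stood at 5.84 against 30.6 FPKM. Lysozyme and antimicrobial genes included sysm-1, 3.44-fold lower in HT115_1, and cnc-7, 2.34-fold higher. In HT115_2, clec-209 (78.4 FPKM) was 2.54-fold and sysm-1 1.75-fold higher than in OP50.

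Metabolic and detoxification genes differed in both directions. The mitochondrial acyl-CoA synthetase gene acs-2 (WBGene00009221), which acts in fatty acid oxidation, was 2.83-fold lower in HT115_1 at 8.96 against 26.2 FPKM, and was within 2-fold of OP50 in HT115_2. The glyoxylate cycle gene icl-1 was 2.42-fold lower at 57 against 139 FPKM (61.8 in HT115_2). The glutathione transferase gene gsto-1 was 3.25-fold higher at 27.4 against 8.08 FPKM, and hrg-7, encoding a secreted aspartic protease-like protein, was 3.25-fold higher at 196 against 59.8 FPKM, and both were also higher in HT115_2, 4.37- and 3.54-fold. The propionate shunt is a pathway that breaks down propionate without vitamin B12. The 7 genes listed for it included 0 genes past 2-fold, with a median of -0.13 relative to all genes. The 6 vitellogenin genes, encoding yolk proteins, also included 0, whereas 5 were lower in HT115_2 than in OP50. None of the 12 cadmium and metal response genes passed 2-fold, and mtl-1 stood at 11.4 against 7.23 FPKM. In HT115_2, 2 of the 7 propionate shunt genes and 2 of the 12 metal response genes were higher than in OP50. Histone genes (median -0.35), neuron markers (-0.28), glutathione transferases (-0.28) and ribosomal protein genes (-0.27) lay below percentile 0.1, and of these lists the ribosomal proteins (-0.63) and histones (-0.37) also had medians below that of all genes in HT115_2. The authors' deposited table listed 715 genes higher and 11 lower at 2-fold with a probability of at least 0.8, a threshold applied here.

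**Figure D1:**
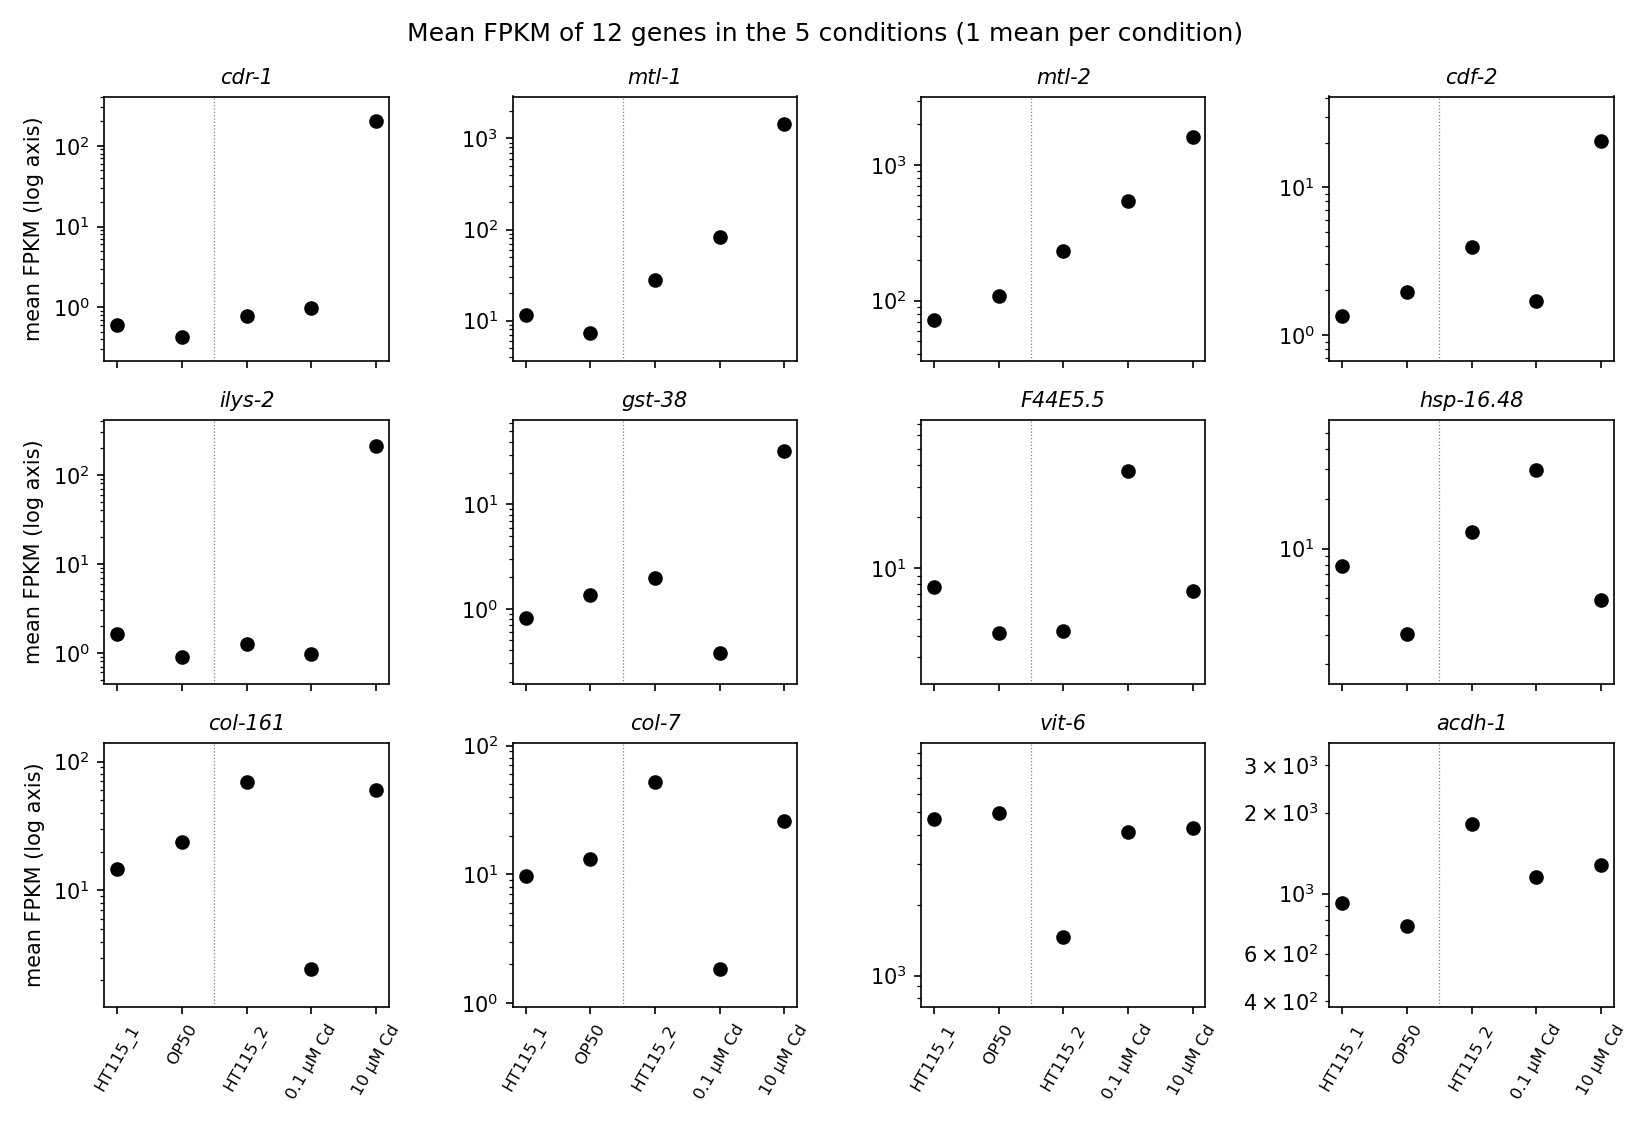
Mean FPKM (log axis) of 12 of the named genes in the 5 conditions, with 1 point per condition and no error because only means were used; the dotted line separates the diet pair from the cadmium set, and axes differ between genes. The metallothionein gene mtl-2 stands at 233 FPKM in HT115_2, 545 at 0.1 µM and 1610 at 10 µM, whereas cdr-1 stands at 0.783, 0.970 and 204 FPKM.

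Cadmium at 10 µM against HT115_2 asks what the higher dose does. Of the 13 metal response genes, 6 were 2-fold higher and 7 were within 2-fold. The largest ratio was that of cdr-1 (WBGene00000412), a cadmium-responsive gene of the gut, at 204 against 0.783 FPKM (159-fold). The metallothionein genes mtl-1 (WBGene00003473) and mtl-2 (WBGene00003474), whose products bind cadmium, stood at 1444 against 28.3 FPKM (50.2-fold) and 1610 against 233 FPKM (6.89-fold). Against HT115_1, cdr-1, mtl-1 and mtl-2 were 185-, 121- and 22.3-fold higher. The zinc transporter genes cdf-2, ttm-1 and zipt-2.3 were 4.70-, 2.43- and 2.47-fold higher. Against HT115_1, ttm-1 was within 2-fold. The list had a median 0.96 above all genes (percentile 100), while cdr-7 (-0.96), cdr-6 (-0.74) and pcs-1 (-0.17) had log2 ratios below 0.

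Of 13132 genes compared at 10 µM, 469 were 2-fold higher and 807 lower (36.8% higher among those past 2-fold). The median of all genes was -0.29, and after rescaling by the median ratio the split was 1038 higher and 243 lower. Against HT115_1 as the control, processed in another set, 552 were higher and 193 lower. The authors' deposited table listed 92 higher and 102 lower at 2-fold with a probability of at least 0.8, on a probability scale that differs from that of the other tables.

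Genes of detoxification and defence made up 5 of the 8 other named genes with the 10 largest ratios at 10 µM. The invertebrate lysozyme genes ilys-2 (WBGene00016669) and ilys-3 stood at 208 against 1.25 FPKM and 40.0 against 1.08 FPKM. Other antimicrobial genes were lower, such as the caenacin genes cnc-7 (4.30 against 41.5 FPKM) and cnc-2 (3.93 against 25.2 FPKM). In all, 9 of the 54 lysozyme, saposin-like and antimicrobial genes were higher and 15 lower, but 14 of 53 were higher and 3 lower against HT115_1, where cnc-7 was within 2-fold. Among cytochrome P450 genes, 5 of 46 were higher, led by cyp-13A4 (35.4 against 2.07 FPKM) and cyp-14A4, and 5 were lower, including cyp-25A1. Against HT115_1 these counts were 10 and 1 of 43, and cyp-25A1 was within 2-fold. The UDP-glycosyltransferase gene ugt-32 was 21.2-fold higher, and 5 of 53 genes of that family were higher against 1 lower (11 and 0 of 51 against HT115_1). The glutathione transferase gene gst-38 stood at 32.4 against 1.96 FPKM, with 3 of 38 in its family higher and 2 lower (9 and 0 of 37 against HT115_1). Of 36 ABC transporter genes, 5 were higher, including pgp-9 (5.99-fold), and 0 lower (4 and 0 of 35 against HT115_1). The aspartic protease gene asp-14 (276 against 12.5 FPKM) and dod-24 (238 against 11.6 FPKM) were also among the 10 largest, as was the myosin gene myo-1 (13.8 against 0.797 FPKM), which stood at 6.73 FPKM in HT115_1.

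Lipid and tissue genes differed as well. The stearoyl-CoA desaturase gene fat-7 was 3.79-fold lower at 10 µM (58.2 against 222 FPKM), and the acyl-CoA dehydrogenase gene acdh-2 was 3.54-fold lower. The epidermal antimicrobial peptide gene nlp-29 was 4.22-fold lower, and dnc-5 was listed at 0 in all 3 libraries at 10 µM against 30.4 FPKM. The gut cathepsin B gene cpr-1 was 4.93-fold higher (2032 against 412 FPKM) and the aspartic protease gene asp-4 was 2.99-fold lower. In HT115_1, fat-7 (108 FPKM), acdh-2 (22.6), nlp-29 (15.2) and asp-4 (163) were within 2-fold of 10 µM, and dnc-5 stood at 1.89 FPKM there and at 0 in all 3 OP50 libraries. Muscle markers had a median 1.21 above all genes, with 7 of 15 higher and 0 lower, which became 0.79 after centring on gene length. Against HT115_1 their raw median was 0.50 and 0 of 15 passed 2-fold. Oocyte and germ line markers had a median 0.57 above all genes, but a raw median of -0.055 with 0 of 22 past 2-fold against HT115_1. Relative to all genes, early embryo markers had a median of -0.64, with 12 of 31 lower. Against HT115_1 the embryo markers had a raw median of -0.037, with 2 of 23 higher and 0 lower. Collagens, with 15 of 126 higher and 8 lower, and sperm genes, with 1 of 58 in each direction, had raw medians of -0.01 and -0.07, which lie above 0 after either rescaling. Against HT115_1, 59 of 126 collagens were higher and 2 lower (raw median 0.94), and 6 of 60 sperm genes were lower and 0 higher (raw median -0.47). Yolk protein genes had a median 1.44 above all genes, with vit-2 at 4479 against 1728 FPKM. After centring on gene length their median was 0.46 (percentile 93.3). Against HT115_1 the raw median log2 ratio of the yolk protein genes was -0.07.

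Cadmium at 0.1 µM against HT115_2 asks what the weak dose does. Sperm and cuticle genes were lower at 0.1 µM as groups, with 49 of 58 sperm genes and 90 of 124 collagen genes at least 2-fold lower. Relative to all genes, their medians were -2.02 and -1.74 (percentile 0 for both). The collagen gene col-161 (WBGene00000734) stood at 2.47 against 69.7 FPKM (23.6-fold lower), col-7 at 1.85 against 52.4 FPKM, and 7 further collagens were among the 10 lowest named genes. The remaining member of those 10, ssp-9 (WBGene00006038), was listed at 0 at 0.1 µM. The major sperm protein gene msp-64, from a family of near-identical copies among which reads may be shared, stood at 1.95 against 29.9 FPKM. The metallothionein genes mtl-1 (82.4 against 28.3 FPKM) and mtl-2 (545 against 233 FPKM) were 2.88- and 2.33-fold higher (6.96- and 7.56-fold against HT115_1), and cdr-1 stood at 0.970 against 0.783 FPKM.

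Heat shock genes at 0.1 µM had a median 1.09 above all genes (percentile 100), with 7 of 18 higher and 0 lower. Against HT115_1 their raw median was 0.55, where that of all genes was 0.096, with 7 of 18 higher and 0 lower. The Hsp70 gene F44E5.5 stood at 37 against 4.27 FPKM (7.87-fold), and the small heat shock gene hsp-16.41 at 5.18 against 1.05 FPKM. Of the 12 metal response genes, 3 were lower, namely cdr-2, cdr-7 and cdf-2, by 2.03- to 2.07-fold. Against HT115_1, 0 of 12 were lower and 2 were higher, and cdr-2 and cdf-2 had log2 ratios of 0.11 and 0.26. Glutathione transferases had 11 of 36 lower, C-type lectins 24 of 88 lower and 1 higher, and antimicrobial genes 24 of 52 lower and 1 higher. Against HT115_1, 0 of 31 glutathione transferases, 27 of 100 C-type lectins and 4 of 49 antimicrobial genes were lower. The desaturase genes fat-7 and fat-6 were 2.42- and 2.24-fold lower, and lbp-8, encoding a lysosomal lipid-binding protein, was 4.33-fold lower, but all 3 were within 2-fold against HT115_1. Yolk protein genes included 5 of 6 that were higher, such as vit-6 at 4112 against 1464 FPKM, but their raw median was -0.09 against HT115_1.

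At 0.1 µM, 344 of 12923 genes were 2-fold higher and 1814 lower (15.9% higher among those past 2-fold). The median of all genes was -0.30, and after rescaling by the median ratio the split was 902 higher and 1113 lower. With HT115_1 as the control, 231 genes were higher and 942 lower. The authors' deposited table listed 399 genes higher and 2342 lower at 2-fold with a probability of at least 0.8. Log2 ratios increased with gene length across genes, which are not independent replicates (Spearman coefficient 0.59 at 0.1 µM and 0.51 at 10 µM). At 0.1 µM the median ran from -0.92 for genes of up to 500 bases to 0.94 above 5000 bases. The 10 highest named genes, chosen among those with a gene symbol and at least 10 FPKM, were 3198 bases or longer, led by ketn-1 (11.5 against 1.28 FPKM), which encodes the muscle protein kettin, eel-1 and taf-1. The heat shock gene F44E5.5, at 2063 bases, had a larger ratio than any of them. Against HT115_1, ketn-1, eel-1 and taf-1 were within 2-fold, while F44E5.5 was 4.56-fold higher. Of the 10 highest named genes, clec-223 alone was also 2-fold higher against HT115_1, at 64.3 against 27.4 FPKM (2.32-fold). After centring on gene length, the medians were -1.47 for sperm genes, -1.63 for collagens, 0.87 for heat shock genes and 0.33 for yolk protein genes, and 277 genes were higher and 722 lower.

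**Figure D2:**
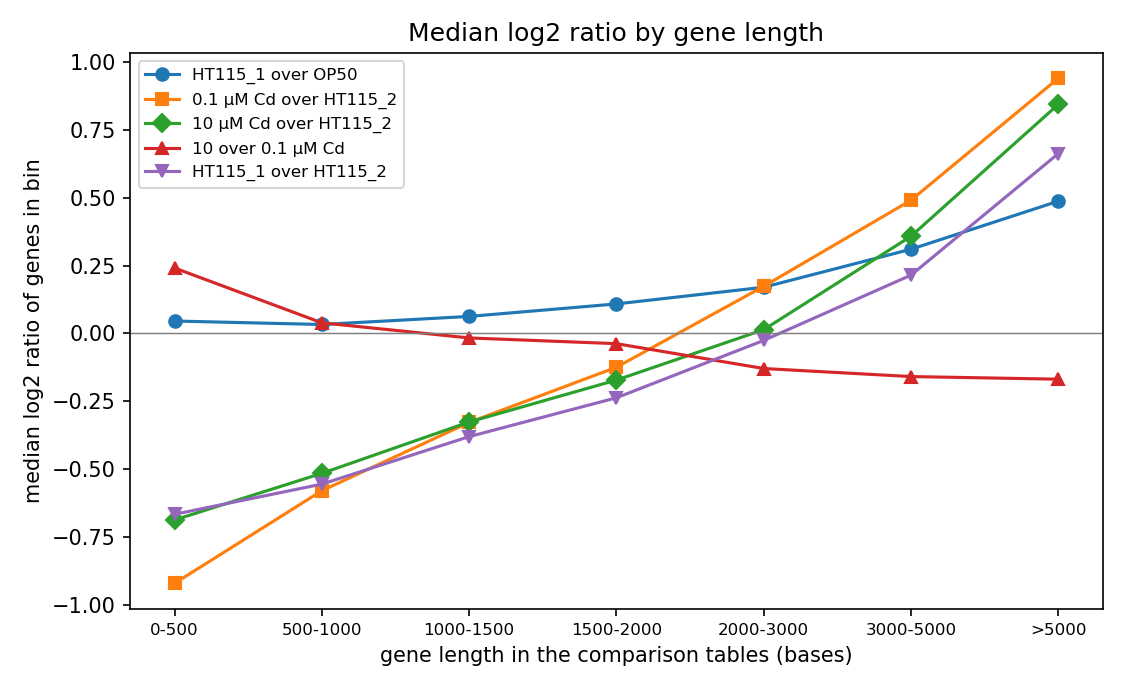
Median log2 ratio of all genes compared in bins of gene length (bases, as listed in the authors' comparison tables), with 1 line per comparison. The 3 comparisons with HT115_2 as reference run from below -0.6 in the shortest bin to above 0.6 in the longest, the diet pair runs from 0.046 to 0.49, and the comparison of the 2 doses runs from 0.24 to -0.17.

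The comparison of 10 µM with 0.1 µM asks what separates the doses and does not involve HT115_2. At 10 µM, 88 of 125 collagen genes and 47 of 56 sperm genes were at least 2-fold higher and 0 in either list were lower. Relative to all genes, their medians were 2.04 and 2.27 (percentile 100 for both). Collagens were represented among the 10 largest ratios by col-73 (108 against 2.80 FPKM), dpy-13 (66.5 against 1.62 FPKM), col-125, col-17 and dpy-4. The metal response genes had 7 of 13 higher at 10 µM and 0 lower, with cdr-1 139-fold, mtl-1 17.4-fold, cdf-2 9.54-fold and mtl-2 2.95-fold higher. Heat shock genes were lower at 10 µM, with 7 of 18 past 2-fold and a median of -0.43 relative to all genes (percentile 0). Examples are hsp-16.48 (4.92 against 29.9 FPKM) and hsp-16.1 (3.54-fold lower).

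Between the doses, 1157 of 12546 genes were 2-fold higher at 10 µM and 180 lower, with a median of all genes of -0.02. The authors' deposited table listed 1452 higher and 279 lower at 2-fold with a probability of at least 0.8. Among defence genes, 19 of 90 C-type lectins were higher at 10 µM, 1 was lower and 70 were within 2-fold, and of 52 antimicrobial genes 19 were higher, 3 lower and 30 within 2-fold. The lysozyme gene ilys-2 was 141-fold higher, ilys-3 stood at 40.0 against 0.257 FPKM with 1 of 3 libraries at 0 at 0.1 µM, and lys-6 was 2.69-fold lower. Glutathione transferases had 7 of 37 higher, including gst-38 at 37.3-fold, and 7 of 51 UDP-glycosyltransferase genes were higher. Gut markers had a median 0.74 above all genes, with cpr-1 5.08-fold and the intestinal actin gene act-5 2.51-fold higher. Yolk protein genes differed by less than 2-fold in all 6 members.

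**Figure D3:**
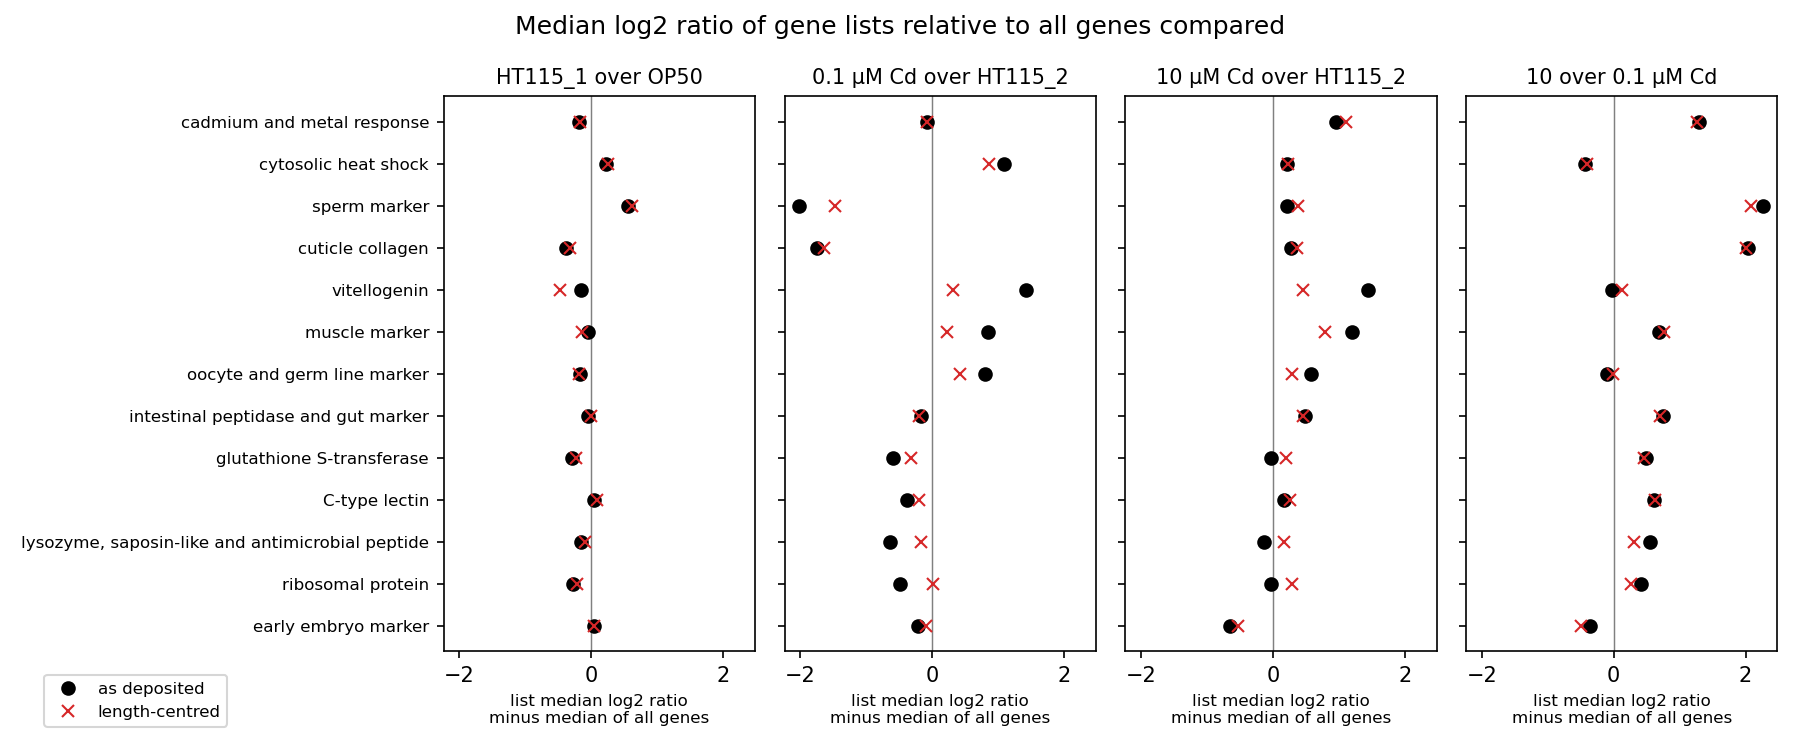
Median log2 ratio of 13 gene lists minus the median of all genes compared, in 4 comparisons, as deposited (dots) and after centring on gene length (crosses). Sperm markers lie at -2.02 at 0.1 µM over HT115_2 and at 0.22 at 10 µM over HT115_2 as deposited; the raw median of the latter is -0.07 and is above 0 after rescaling.

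The 2 doses were compared through their ratios to HT115_2, which both share. Across 12879 genes, which are not independent replicates, the log2 ratios had a Pearson r of 0.453 and a covariance of 0.206. Unchanged groups simulated with the same shared control, with a spread taken from the comparison of the doses, gave an r of 0.501 and a covariance of 0.283. An r of that size follows from giving all groups the same spread, whatever the data. The spread used also holds the differences between the doses. Of the genes past 2-fold, 153 were higher at both doses against 10.4 for independent lists, and 330 were lower at both against 113.7. The simulated groups, with 1179 to 1187 genes past 2-fold in each direction, had 372 higher and 368 lower in both. They are not a close reference, since 340 genes were higher and 1814 lower at 0.1 µM, and 395 and 807 at 10 µM. A further 51 were higher at 10 µM and lower at 0.1 µM, and 3 were the reverse, against 7.25 and 7.26 in the simulated groups. Part or all of the overlap may come from the shared control. With HT115_1 as the control of 0.1 µM r was -0.0922, and with it as the control of 10 µM r was -0.121.

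HT115_1 and HT115_2 are the same food in separate conditions, processed by the authors in separate sets. Their ratios show how far these unexposed conditions differ across sets. They are not a measure of no change within a set, and they share HT115_1 or HT115_2 with every other comparison except that of the doses. Of 13119 genes, 286 were 2-fold higher in HT115_1 and 1482 lower, with a median of all genes of -0.33, and after rescaling by the median ratio 849 were higher and 573 lower. Yolk protein genes were higher in HT115_1 (median 1.5 above all genes, 5 of 6 past 2-fold), with vit-6 at 4668 against 1464 FPKM. After centring on gene length their median was 0.66 (percentile 96.2). Collagens were lower as a group, with a median of -0.48 relative to all genes and 56 of 124 past 2-fold, and sperm genes had a median 0.79 above all genes. Muscle markers had 7 of 15 higher in HT115_1, while 13 of 31 early embryo markers, 10 of 36 glutathione transferases and 19 of 52 antimicrobial genes were lower. The metal response genes included 5 of 12 that were lower in HT115_1, with mtl-2 at 71.6 against 233 FPKM. Genes 2-fold different from HT115_2 were set against HT115_1 where listed in both sets and at least 1 FPKM in the dose or HT115_1. At 0.1 µM, 1555 of 1814 lower and 344 of 344 higher genes met this. At 10 µM, 706 of 807 lower and 468 of 469 higher genes did. Genes under 1 FPKM in both the dose and HT115_1 were left out and not counted as failing. Of the genes kept, 690 of 1555 lower at 0.1 µM and 180 of 468 higher at 10 µM were also 2-fold different from HT115_1. For genes higher at 0.1 µM this held for 35 of 344, and for genes lower at 10 µM for 48 of 706. Among the named genes it held for 6 of 29 higher and 18 of 42 lower at 0.1 µM, and for 24 of 37 higher and 4 of 33 lower at 10 µM, in the same direction.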

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

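The tests of recovery in HT115_2 and within housekeeping genes, those of a single library, of dose and of age, and both tests of the 10 highest genes were chosen only after the result was seen. The length test of sperm genes was written down before its own value was seen, but length centring itself was chosen only after the length trend had been seen. The single genes below stand out because the 2 cadmium doses lie on opposite sides of the same control, HT115_2, and the gene lists because the doses lie on opposite sides of matched random lists. The difference between the doses was not tested in any of them, since only means per condition were used, and the shared control enters both sides.

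As lists, C-type lectins lay at percentile 0.01 at 0.1 µM and 99.5 at 10 µM, cuticle collagens at 0 and 100, and sperm genes at 0 and 98.6. The raw medians of these lists were below HT115_2 at both doses, at -0.68 and -0.12 for C-type lectins, -2.04 and -0.012 for collagens, and -2.32 and -0.069 for sperm genes. Among single genes, the log2 ratio to HT115_2 at 0.1 µM and at 10 µM was -1.06 and 4.68 for the lysozyme gene ilys-3, -1.48 and 3.74 for gst-38, and -1.02 and 2.23 for the zinc transporter gene cdf-2. For cuticle genes the pair was -3.21 and 1.77 in dpy-13, -1.24 and 1.63 in bli-1, -3.23 and 1.47 in col-17, -2.59 and 1.42 in col-71, -3.34 and 1.23 in dpy-4, and -3.83 and 1.21 in col-73. It was -2.81 and 1.34 in pud-3 and -2.45 and 1.07 in pud-1.2. The small heat shock gene hsp-16.48 went the other way, with 1.22 and -1.26. Against HT115_1, chosen as a control after the result was seen, ilys-3 and the 6 cuticle genes were again 2-fold lower at 0.1 µM and 2-fold higher at 10 µM. In cdf-2 (0.26 and 3.52), pud-3 (1.05 and 5.20) and pud-1.2 (1.23 and 4.74) both doses were above HT115_1, so their opposite signs rest on HT115_2 alone. At 10 µM hsp-16.48 was then within 2-fold (-0.62), and gst-38 was not compared at 0.1 µM for lack of expression.

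Sperm and collagen genes had a lower median FPKM at 0.1 µM (2.09 and 2.02) than in any other condition, and the length trend of the ratios to HT115_2 is argued against as the whole cause, because the median of sperm genes after centring on length was still -1.47. A single odd library is argued against too: 75% of sperm genes (39 of 52) and 48.2% of collagens (54 of 112) had a 0.1 µM mean more than 3-fold below the lowest other mean, against 3.21% of all 11000 genes, and a mean of 3 libraries cannot lie that low through 1 of them if the others match the other conditions. An effect of cadmium that grows with dose is argued against by the median of sperm genes at 10 µM against HT115_2, which was -0.069. Whether animals of another adult age in the 0.1 µM harvest account for the pattern cannot be told. Yolk protein genes differed between the doses by a median of -0.049. That value does not decide it, because how these genes change with adult age was not measured here. The harvests are also the conditions themselves, and the spread between replicates was not used. A response limited to the weak dose also stays open and was not tested.

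Log2 ratios increased with gene length in all 3 comparisons with HT115_2 as the reference. A candidate explanation is that long transcripts were recovered less well in the HT115_2 libraries: the smallest Spearman coefficient among the 3 was 0.45, while the comparisons without HT115_2 gave 0.19 on the diet pair, a weaker trend of the same sign that HT115_2 cannot explain, and -0.16 between the doses. Cadmium cannot be the cause of the part seen between the HT115 conditions, since neither was exposed. That short and long gene classes differ for other reasons stays open. Across 145 ribosomal protein, proteasome and oxidative phosphorylation genes the coefficient was 0.789 at 0.1 µM, 0.568 at 10 µM and 0.349 between the HT115 conditions. It was 0.204 on the diet pair and -0.393 between the doses. These 3 classes were pooled and had unlike medians at 0.1 µM (-0.785, -0.159 and -0.536), so the test cannot separate class from length. Within the 15 muscle markers the coefficient was 0.889 at 0.1 µM, 0.929 at 10 µM and 0.896 between the HT115 conditions. There it was also 0.818 on the diet pair, without HT115_2, and 0.168 between the doses. A biological difference of the animals in HT115_2 was not tested and stays open.

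The 10 named genes highest at 10 µM, among them cdr-1, mtl-1 and ilys-2, could have been raised by a low value in HT115_2 alone. Against both 0.1 µM and HT115_1, 9 of the 10 were 2-fold higher as well, and the exception, myo-1, had a log2 ratio of 0.98 to HT115_1. The length trend is argued against for 9 of the 10, which are 373 to 1584 bases long, where the running median of all genes over length lies below 0, and stays open in part for myo-1, at 6490 bases. A test written earlier, whether the ratios stay past 2-fold after centring, was replaced because ratios this large could not fail it. A response to 10 µM cadmium remains as a hypothesis for the 9, since the values were found and tested on the same means and their spread between replicates was not used here.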

How the results depend on the processing

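Length centring, HT115_1 as the control and HT115_2 as the HT115 condition of the diet pair were chosen only after the results were seen. The other alternatives here were planned, but the threshold on the authors' probability was chosen after the scores had been seen. The cause was not tested for any of the shifts below. No paired analysis was possible because the values are means per condition and no result comes from a test. For the same reason DESeq2, edgeR and limma, other sets of samples in the fit, leaving out each replicate and the replicate block were not run. The depth of about 11100000 to 11300000 fragments per library limits weakly expressed genes most, but its effect on a mean cannot be separated from the spread between replicates.

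Counts of genes are given as higher and lower for HT115_1 over OP50, 0.1 µM over HT115_2, 10 µM over HT115_2, 10 over 0.1 µM, and HT115_1 over HT115_2, in that order. At 1.5-fold they were 1732 and 256, 1148 and 4196, 1357 and 3402, 2191 and 1159, and 995 and 4135. At 4-fold they were 97 and 10, 10 and 361, 72 and 23, 340 and 12, and 16 and 70. The diet count was 795 higher with a pseudocount of 0.1, and 305 higher and 45 lower with 1. At 5 FPKM the diet counts were 188 higher and 38 lower, 957 were lower at 0.1 µM, 524 higher at 10 over 0.1 µM, and 184 higher in HT115_1 over HT115_2. Rescaling by the median ratio gave 902 and 1113 at 0.1 µM, 1038 and 243 at 10 µM, and 849 and 573 between the HT115 conditions; the trimmed mean gave 907 and 1111, 1019 and 247, and 852 and 573. With the probability of the authors' deposited tables, 11 were lower on HT115, 92 higher and 102 lower at 10 µM, and 279 lower between the doses. Length centring left 722 lower at 0.1 µM, 100 lower at 10 µM, and 533 and 293 between the HT115 conditions. With HT115_1 as the control, 942 were lower at 0.1 µM and 193 at 10 µM. With HT115_2 against OP50, 2648 were higher and 193 lower. Counts without the low-value filter stayed within 1.5 times in all 10 cases. The number of lists beyond the outer 2.5% on either side stayed within 1.5 times under each alternative run.

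For lists beyond the outer 2.5% of random lists on either side, raw medians changed sign as follows, and sign changes of other lists are left out. On the diet pair, antimicrobial genes were at 0.058 without the low-value filter. Insulin and dauer genes were at -0.052, -0.064 and -0.093, and gut markers at -0.042, -0.054 and -0.0028, with the median ratio, the trimmed mean and length centring. With HT115_2 against OP50, metal response genes were at 0.54, glutathione transferases at 0.66, antioxidant genes at 0.43, DAF-16 targets at 0.34, antimicrobial genes at 0.74, collagens at 0.60, neuron markers at 0.61, oxidative phosphorylation at 0.089 and histones at 0.14. The median of all genes was 0.52 in that comparison. ABC transporters were at 0.22, 0.22 and 0.16 at 0.1 µM and at 0.27, 0.27 and 0.22 at 10 µM with the median ratio, the trimmed mean and HT115_1 as the control. At 0.1 µM with HT115_1 as the control, antioxidant genes were at 0.021, vitellogenins at -0.088, fatty acid synthesis at 0.014, lipid breakdown at 0.070, antimicrobial genes at 0.033, insulin and dauer genes at 0.018, muscle at -0.39 and neuron markers at 0.014. Muscle was at -0.30 at 5 FPKM, and ribosomal protein and histone genes were at 0.021 and 0.039 after length centring. At 10 µM with HT115_1 as the control, vitellogenins were at -0.067, lipid breakdown at 0.026, C-type lectins at 0.29, collagens at 0.94 and germ line markers at -0.055. With the median ratio, the trimmed mean and length centring at 10 µM, C-type lectins were at 0.19, 0.19 and 0.26, collagens at 0.28, 0.27 and 0.36, and sperm genes at 0.23, 0.22 and 0.38. Collagens were at 0.038 at 5 FPKM. Between the HT115 conditions, ribosomal protein genes were at 0.30, 0.30 and 0.58 under those alternatives.

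Among genes named for a comparison and past 2-fold in it, 34 log2 ratios changed sign, 25 with HT115_1 as the control and 9 with HT115_2 against OP50, and sign changes of named genes within 2-fold are left out. With HT115_2 against OP50 these were pud-1.2 (1.02), both copies of clec-209 (1.34) and of pud-2.2 (1.76), cah-4 (0.79), sysm-1 (0.81), irg-5 (0.33) and col-74 (-1.06). At 0.1 µM these were ketn-1 (-0.23), cdr-2 (0.11), cdf-2 (0.26), lea-1 (-0.10), vit-1 (-0.064), vit-2 (-0.22), vit-5 (-0.11), vit-6 (-0.18), both copies of clec-209 (1.59), cnc-2 (0.063) and unc-54 (-0.43). At 10 µM these were drd-10 (0.31), ubl-5 (0.094), cyp-34A8 (0.57), gst-42 (0.24), ugt-53 (0.046), vit-2 (-0.044), vit-6 (-0.13), elo-6 (0.17), lbp-2 (0.10), ins-28 (0.19), col-158 (0.17), cbd-1 (-0.089) and his-38 (0.18). The correlation of the ratios at both doses was 0.423 with a pseudocount of 0.1, 0.530 at 5 FPKM, 0.548 for genes at or above the median expression, 0.233 after length centring, and -0.0922 with HT115_1 as the control of 0.1 µM.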

Other observations

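The values after length centring and those that set the cadmium doses against HT115_1 or HT115_2 beside OP50 in this part were chosen only after the results were seen. Endoplasmic reticulum stress genes had a median 0.56 above all genes at 0.1 µM over HT115_2 and 0.46 at 10 µM over HT115_2, and after length centring these were 0.20 and 0.17. Against HT115_1 their raw medians were 0.13 and 0.016, where those of all genes were 0.096 and 0.034. Among their 16 members the chaperone gene hsp-3 alone passed 2-fold at 10 µM, at 292 against 142 FPKM, and 0 did so at 0.1 µM. Mitochondrial stress genes had 1 of 9 members past 2-fold at 10 µM, ubl-5, at 48.5 against 98.5 FPKM. Antioxidant genes had 4 of 29 lower at 0.1 µM, among them the catalase gene ctl-1 at 6.27 against 17.1 FPKM and the ferritin gene ftn-2 at 223 against 475 FPKM. Hypoxia and sulfide response genes had 1 of 10 past 2-fold at 10 µM, the cysteine dioxygenase gene cdo-1, at 30.3 against 65.5 FPKM. Against HT115_1, hsp-3 (262 FPKM), ubl-5 (45.4), ftn-2 (256) and cdo-1 (30.9) were within 2-fold of these values, and ctl-1 (13.5) was not.

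Metabolic and housekeeping lists were mostly within 2-fold in both cadmium comparisons. All 7 propionate shunt genes stayed within 2-fold of HT115_2 at both doses, with acdh-1 at 1156 FPKM at 0.1 µM and 1279 FPKM at 10 µM against 1812 FPKM. All 33 proteasome genes were within 2-fold in each of the 5 comparisons. Ribosomal protein genes had 21 of 80 lower at 0.1 µM, with a median of -0.49 relative to all genes that became 0.02 after length centring, and the shortest of them, such as rpl-41.2, lay lowest. Against HT115_1, 12 of 80 were lower with a raw median of -0.75, and at 10 over 0.1 µM the median was 0.42 above all genes and 0.26 after length centring. The insulin receptor gene daf-2 was 2.16-fold higher at 0.1 µM but within 2-fold of HT115_1, while 16 of the 33 insulin and dauer genes were lower, among them the short insulin-like gene ins-27 at 5.94 against 28.4 FPKM. Against HT115_1 at 0.1 µM, 3 of 29 insulin and dauer genes were lower, with a raw median of 0.018. On the diet pair, ins-31 stood at 8.48 FPKM in HT115_1 against 0.923 in OP50, and at 2.55 FPKM in HT115_2.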
